A study of Mus musculus with 4 samples.

How the data were processed

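Total RNA had been isolated from treated skin with a kit for lipid-rich tissue, and 200 ng per sample had been labelled with biotin for 3′ expression arrays, per the labels' protocols. The deposited table holds 45101 probe sets on 4 arrays as linear scaled signals, that is, array intensity with no logarithm taken. How the intensity values were made from the scans, and with which software, is not given in the sources used here. Tested on the deposited values, the mean without the highest and lowest 2% of probe sets was 500 on each array, while the quantiles differed between arrays, so the deposited intensity values had been scaled but not quantile normalized. They carried no detection calls. As a guide to background, the TrpnX control probe sets, made for bacterial transcripts, had signals of 1.55 to 24.

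Probe sets were named from the platform's annotation, and symbols were updated through the Entrez gene ID to the RefSeq gene table of the GRCm38.p6 assembly. No coordinates were used. Of the probe sets, 64 were array controls and were left out, 34945 had 1 gene symbol (34741 of them matched by ID), 932 had several, and 9160 were not listed and stay unnamed here. Each gene was represented by the probe set with the highest mean over all 4 arrays, among those with 1 symbol, which gave 18193 genes. More than 1 probe set was carried by 9010 genes. Among 92 genes that the rule below names, 24 had other probe sets, 48 in all, and 8 of these went the other way. For 4 of the 92 (Hdc, Lor, S100a8 and Saa1), the probe set has a suffix that marks possible cross-hybridisation.

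Signals were taken as log2(signal + 16) with no further normalization and no filter on dim genes. The groups, vehicle and MC903, come from the labels, with 2 arrays each. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The fit had 2 residual and 2.32 prior degrees of freedom. A prior that follows the signal (3.72 prior degrees of freedom) was an alternative. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 40 lists of at least 5 measured genes, with a correlation estimated per list and fry as alternatives. The lists covered alarmins, type 2 genes, vitamin D targets, cornified envelope, wound keratinocytes, antimicrobials, epidermal lipid, sebaceous gland, the IL-17 and IL-22 axis, chemokines, interferon response, acute phase, lipid mediators, matrix, cell cycle, itch, tight junctions, immediate early genes, circadian clock and markers of the cell types that skin can hold. Genes at least 2-fold apart in each of the 4 pairings of an MC903 with a vehicle array were counted without a test.

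Named genes were fixed by rule before the data were examined, as were the lists, tests and the settings to be varied. The rule took the 10 genes with the largest differences each way among those passing the main test (none passed), up to 4 passing members of each list or, with fewer than 2 passing, the 2 with the largest absolute differences, and 21 genes of interest in this setting. Alternatives were quantile normalization, centring on array medians, added constants of 1 and 64, leaving out the 25% or the 50% of genes with the lowest mean signals, averaging probe sets, testing probe sets singly, a robust prior, other thresholds, a replicate block and leaving out each array. Following the signal-dependent count through these settings was added after the data had been seen, as were some settings of the pairwise counts and of camera. With 1 array left out, the lone array is assumed to vary like the other group.

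The gene test was tested on simulated data for MC903 against vehicle, 18193 genes of which 200 were changed, 20 times. Simulated genes varied independently, with a spread drawn from the fit that follows the signal, and the 200 came from genes above the median signal. The constant prior recovered 71.4% of 4-fold and 97.85% of 16-fold changes with a median of 6 false calls, and the prior that follows the signal recovered 91.95% and 99.45% with 12. This design favours the prior that follows the signal, so these rates do not rank the 2 priors. Nor do they give the recovery on the real arrays, where the constant prior called 0 genes. Camera gave a p below 0.05 in 100% of simulations for a list of 30 genes shifted by 1 with either correlation, and in 0% for an unshifted list. Because the simulated genes varied independently, this says nothing of lists whose genes move together. Estimated correlations in the real lists reached 0.829, in the mitotic cell cycle list. No 2 arrays held identical values. The replicate numbers do not pair the samples in the labels.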

Results

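Transcripts of mouse skin were measured on 3′ expression arrays, 2 from skin treated with vehicle (ethanol) and 2 from skin treated with MC903. MC903, or calcipotriol, is a vitamin D analogue that inflames mouse skin in a way resembling atopic dermatitis. Female BALB/c mice had first been sensitised through the ear skin to ovalbumin, an egg-white protein, and then given it by mouth. MC903 or vehicle was put on the skin between 2 such oral challenges, and RNA was taken from the treated skin after the later one. The comparison asks which transcripts of the treated skin differed between MC903 and vehicle at that point. On each array the signals were scaled to a trimmed mean of 500, and the median probe-set signals were 109 and 99.7 in vehicle and 90.2 and 99.6 in MC903. Nothing states that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

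MC903-treated skin carried far more transcript of Cyp24a1, the enzyme that inactivates vitamin D hormones, and of keratinocyte activation genes, and far less transcript of hair shaft genes. Cyp24a1 had signals of 12.7 and 40.8 in vehicle and of 17297 and 10385 in MC903, a log2 difference of 8.38 ± 0.44 (SE, n = 2 per group). Its size depends on the constant of 16 added to each signal, since 12.7 lies within the range of the TrpnX controls (1.55 to 24), bacterial sequences taken as background. Krt6b, a keratin of wounded and hyperproliferating epidermis, differed by 6.70 ± 0.48, with 1 MC903 signal (43037) close to the highest of its array (50150), where a difference can be compressed. Its partner keratin Krt16 differed by 4.41 ± 0.27. At the other end, the hair keratin Krt33b was lower by a log2 difference of -5.20 ± 0.56, with 1 MC903 signal (17.9) within the range of the TrpnX controls, and the hair keratin-associated protein Krtap8-1 by -5.47 ± 0.79. In all 4 pairings of an MC903 with a vehicle array, 211 genes were at least 2-fold higher and 148 at least 2-fold lower. The other 2 ways of splitting the arrays gave 15 higher and 33 lower, and 18 higher and 40 lower. At least 16-fold differences in all 4 pairings were found for 11 genes higher and 8 lower with MC903, and for 0 genes in either of the other splits.

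Of 18193 genes tested, limma with a constant prior variance called 0 at an adjusted p below 0.05. The smallest adjusted p was 0.0561, and 15 higher and 6 lower genes lay below 0.1. Without adjustment, 1241 genes were higher and 1526 lower at a p below 0.05, 2767 in all against 909.7 expected by chance. Genes do not vary independently, so how far that count can stray by chance is not known. When limma's prior variance followed the signal, 98 genes were called higher and 70 lower, Cyp24a1 (adjusted p = 0.0038), Krt16 (adjusted p = 0.0042) and Krt6b (adjusted p = 0.0069) among them. That count depended on single arrays, with 7 higher and 8 lower without vehicle replicate 1, 5 higher and 0 lower without vehicle replicate 2, and 546 higher and 400 lower without MC903 replicate 2. An exact permutation test of 2 against 2 arrays cannot go below a two-sided p of 0.333. Differences are on the log2(signal + 16) scale, which understates those of dim genes.

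**Figure D1:**
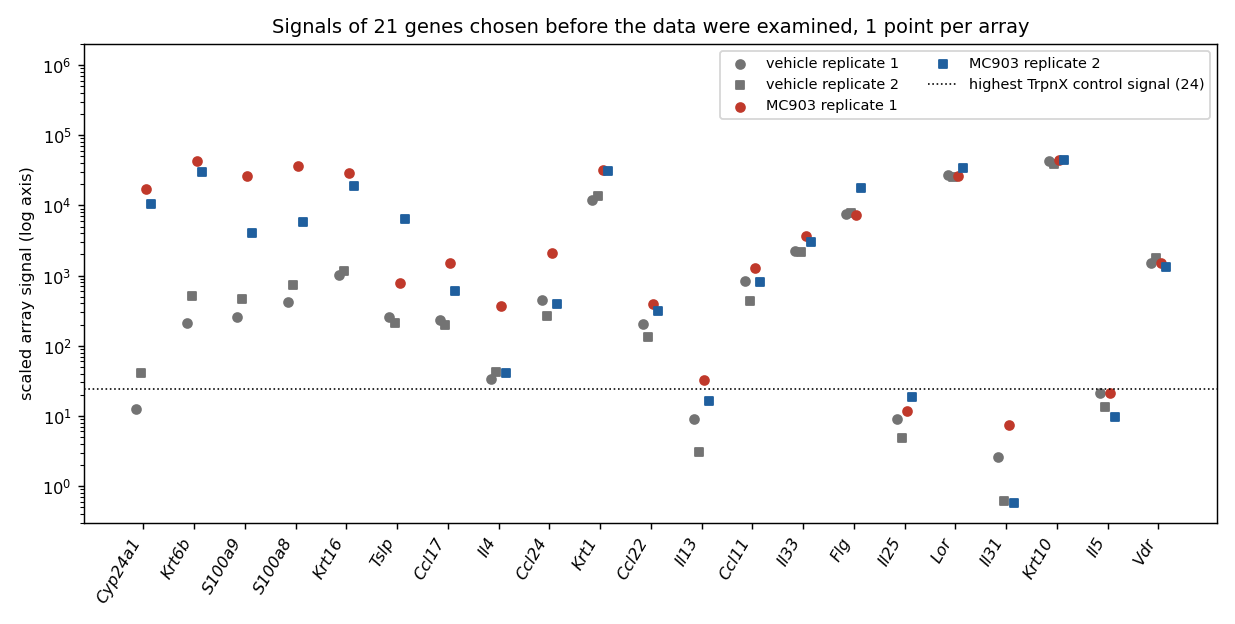
Scaled array signal (log axis) of 21 genes chosen before the data were examined, with 1 point per array for 2 vehicle and 2 MC903 arrays and genes ordered by log2 difference. The dotted line is the highest signal of the TrpnX control probe sets, 24. Cyp24a1 lies at 12.7 and 40.8 in vehicle and at 17297 and 10385 in MC903, whereas Il25, Il31 and Il5 lie at or below the dotted line on every array.

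Gene groups were compared through 40 lists fixed before the data were examined. With limma's camera and a preset correlation, 25 lists were called higher and 4 lower with MC903. With a correlation estimated for each list 0 were called, the smallest adjusted p being 0.39, and 3 of 40 lay below 0.05 before adjustment. That second test also rests on the 2 residual degrees of freedom, so it could hardly pass the threshold. Its 0 calls therefore cannot say whether genes that move together made the first calls. For dendritic cell genes the estimated correlation was 0.0178, near the preset 0.01, yet camera's unadjusted p was 0.0239 against 6.6e-12. fry, which asks only whether a list's genes move one way, also called 0 lists, with a smallest adjusted p of 0.11. Over all genes tested, limma with a constant prior called 0 members of any list. Calls adjusted over the list alone came to 113 higher and 44 lower summed over the lists, to 42 and 31 without vehicle replicate 1, and to 54 and 33 without vehicle replicate 2. Without MC903 replicate 2 they came to 245 and 68. A median given for 1 MC903 array is against the mean of both vehicle arrays and is also the value with the other MC903 array left out.

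**Figure D2:**
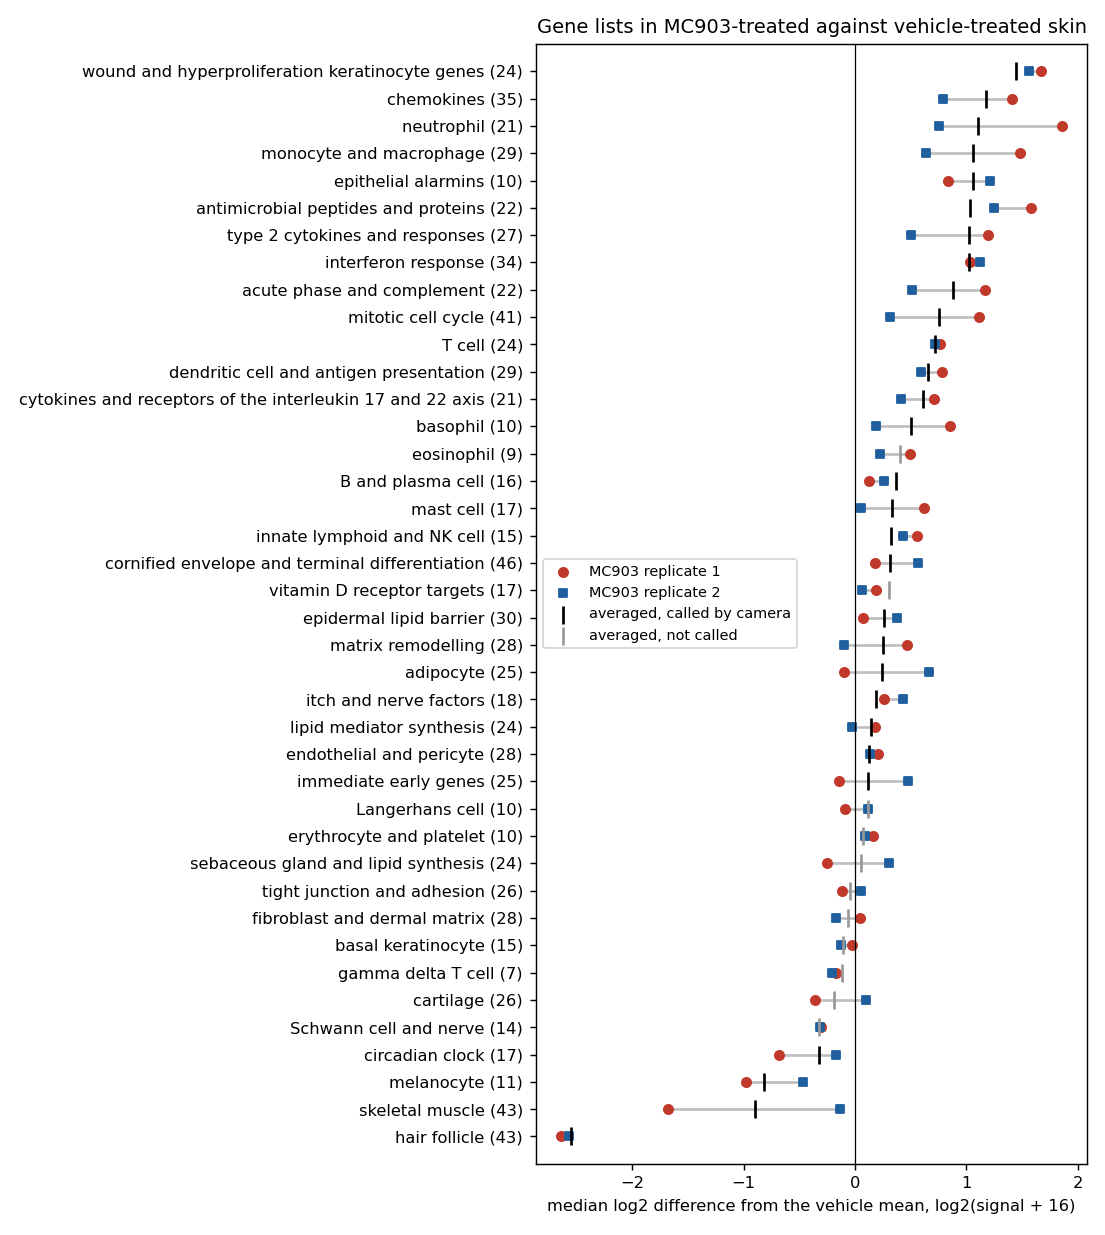
Median over each list's measured genes (their number in parentheses) of the log2 difference from the vehicle mean, on the log2(signal + 16) scale, for each of 2 MC903 arrays (points) and for both averaged (tick, black where camera's adjusted p with the preset correlation is below 0.05). The hair follicle list lies at -2.64 and -2.57 in the MC903 arrays, and the skeletal muscle list at -1.68 and -0.13.

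Keratinocyte genes of wounding and hyperproliferation were shifted upward as a list, with a median log2 difference of 1.44 over 24 genes (camera, adjusted p = 4.64e-11; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, 13 were called higher and 1 lower by limma, against 0 over all genes and 12 higher with the intensity trend. Stfa2l1, of the stefin family of cysteine protease inhibitors, stood at 41.3 and 64.9 in vehicle and at 19577 and 5858 in MC903. Sprr2f, a small proline-rich protein of the cornified envelope, stood at 35.7 and 39.5 in vehicle and at 15899 and 2116 in MC903. Members of the Sprr2 and stefin families are close in sequence, and how far each probe set reports its own gene is uncertain. Markers of basal keratinocytes, the dividing layer of the epidermis, had a median difference of -0.11 over 15 genes and were not called (camera, adjusted p = 0.268), Col7a1 differing by -0.84 ± 0.21 and Dst by -0.65 ± 0.15.

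Cornified envelope and terminal differentiation genes were also shifted upward, by a median of 0.32 over 46 genes (camera, adjusted p = 2.24e-10; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, limma called 14 of them higher and 0 lower, against 0 over all genes and 4 over the list alone without either vehicle array. The medians of the MC903 arrays were 0.18 and 0.57. Lce3f, a late cornified envelope gene, differed by 4.51 ± 0.37 and Rptn, which encodes the matrix protein repetin, by 4.08 ± 0.28, though the other 2 probe sets of Rptn went the other way. Among the main structural genes of the layer, Krt1 differed by 1.30 ± 0.17 (limma with intensity trend, adjusted p = 0.0236). Its partner Krt10 differed by 0.14 ± 0.15, but its signals of 39062 to 45067 lay close to the highest of each array (41771 to 50150), where a difference can be compressed, as did the signal of Krt6b in MC903 replicate 1 (43037). Lor, the gene of loricrin, differed by 0.17 ± 0.20 on a probe set whose suffix marks possible cross-hybridisation, and 1 of its 2 other probe sets went the other way. Flg, the gene of filaggrin, stood at 7435 and 7828 in vehicle and at 7333 and 17784 in MC903, so that its difference of 0.58 ± 0.46 became -0.06 without MC903 replicate 2. Without the same array that of Lor became -0.01.

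Antimicrobial genes had a median difference of 1.03 over 22 genes (camera, adjusted p = 3.22e-09; adjusted p = 0.39 with an estimated correlation), 8 of them called higher by limma when adjusted over the list alone (5 without vehicle replicate 1) and 0 over all genes. Their medians in the MC903 arrays were 1.58 and 1.25. The beta-defensin Defb3 stood at 4.79, within the range of the TrpnX controls, and 44.6 in vehicle and at 1505 and 1050 in MC903. S100a8 and S100a9, the subunits of calprotectin, differed by 4.69 ± 0.95 and 4.85 ± 0.97, and their MC903 signals were unequal, S100a8 standing at 36943 and 5891. The probe set of S100a8 has a suffix that marks possible cross-hybridisation. Genes of the epidermal lipid barrier differed by a median of 0.26 over 30 genes (camera, adjusted p = 0.000127; adjusted p = 0.52 with an estimated correlation), and 2 were called higher adjusted over the list alone (0 without either vehicle array) against 0 over all genes. These were Degs2, a sphingolipid desaturase and hydroxylase (2.27 ± 0.24), and Ugcg, the glucosylceramide synthase (1.15 ± 0.19). The call of the lipid barrier list ended without MC903 replicate 2, with a median of 0.07 (camera, adjusted p = 0.138). Tight junction and adhesion genes were not called (median -0.04 over 26 genes, camera, adjusted p = 0.79, with median and test of opposite sign), although the connexins Gjb6 and Gjb2 differed by 2.74 ± 0.52 and 1.60 ± 0.62 (Gjb2 by 0.83 without MC903 replicate 1).

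Hair follicle genes were shifted downward, by a median of -2.56 over 43 genes (camera, adjusted p = 1.72e-18; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, limma called 32 lower and 1 higher, against 0 over all genes and 22 lower and 1 higher with the intensity trend, and 37 were lower in both MC903 arrays than in both vehicle arrays. The medians of the 2 MC903 arrays were -2.64 and -2.57. Krtap8-1 stood at 11821 and 18217 in vehicle and at 694 and 139 in MC903. Melanocyte markers were shifted the same way (median -0.82 over 11 genes, camera, adjusted p = 5.77e-06; adjusted p = 0.39 with an estimated correlation). Of these, 4 were called lower adjusted over the list alone, 0 without vehicle replicate 1 or MC903 replicate 1, and 0 over all genes. The pigment enzymes Tyrp1 and Tyr differed by -1.39 ± 0.25 and -1.30 ± 0.22, and the MC903 medians were -0.98 and -0.47. Genes of the sebaceous gland and of lipid synthesis had a median of 0.05 over 24 genes and were not called (camera, adjusted p = 0.45), Plin2, a lipid droplet protein, differing by 0.61 ± 0.15 while Fabp5, a fatty acid binding protein, had MC903 signals of 50150 and 45897 at or near the highest of those arrays (50150 and 46859), against 35041 and 32698 in vehicle, so its difference is not given. The sebaceous list's median was 0.30 without MC903 replicate 1, where it was called (camera, adjusted p = 0.00162), and -0.25 without MC903 replicate 2. Skeletal muscle markers moved with the hair follicle list in 1 MC903 array, with medians of -1.68 and -0.13.

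Epithelial alarmins, the cytokines that injured epithelium releases, had a median difference of 1.06 over 10 genes (camera, adjusted p = 5.78e-07; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone 8 of 10 were called higher by limma and over all genes 0, and the 8 came to 0 when either vehicle array was left out. Tslp, which drives type 2 responses, stood at 253 and 209 in vehicle and at 777 and 6313 in MC903 (3.19 ± 1.03, but 1.69 without MC903 replicate 2 and 4.69 without MC903 replicate 1). Il1b differed by 2.91 ± 0.79 (1.78 without MC903 replicate 1) and Il33 by 0.60 ± 0.18, whereas Il25 had signals of 4.90 to 18.4, within the range of the TrpnX bacterial controls (1.55 to 24).

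Type 2 cytokine and response genes were shifted upward, with a median of 1.03 over 27 genes (camera, adjusted p = 1.37e-06; adjusted p = 0.42 with an estimated correlation), and limma called 0 of them both over the list alone and over all genes, but 14 higher over the list alone without MC903 replicate 2. The medians of the MC903 arrays were 1.195 and 0.50. The cytokine genes themselves were dim. Il4 stood at 33.5 and 42.2 in vehicle and at 364 and 41.1 in MC903, so its difference of 1.45 ± 0.95 came from 1 array. Il13 stood at 9.14 and 3.11 in vehicle and at 32.9 and 16.5 in MC903, and Il5 and Il31 had signals below 24, the highest of the TrpnX controls, on every array. The largest differences of the list belonged to chitinase-like genes of type 2 inflammation. Chil4 stood at 25.04 and 30.6 in vehicle against 7536 and 843 in MC903 (5.86 ± 1.08). Chil3 stood at 115 and 23.4 in vehicle, the second within the range of the TrpnX controls, against 7635 and 665 in MC903. Another probe set carries the symbols of both genes, and how far each probe set reports its own gene is uncertain. Among the chemokines that attract type 2 cells, Ccl17 differed by 2.08 ± 0.47, Ccl22 by 1.03 ± 0.27, Ccl24 by 1.37 ± 0.85 and Ccl11 by 0.75 ± 0.41, and for Ccl24 and Ccl11 the groups overlapped.

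Itch and nerve factors had a median of 0.19 over 18 genes (camera, adjusted p = 0.0151; adjusted p = 0.39 with an estimated correlation), with 4 called higher and 1 lower by limma over the list alone, 0 without either vehicle array, and 0 over all genes. The itch list's medians in the MC903 arrays were 0.26 and 0.43. The kallikrein protease Klk6 differed by 2.63 ± 0.37. Il31ra, a subunit of the IL-31 receptor, stood at 8.17 and 7.22 in vehicle, within the range of the TrpnX controls, and at 42.4 and 67.3 in MC903, its other probe set going the other way. The itch list's call ended when members of several lists were left out, with a median of -0.07 (camera, adjusted p = 0.162), and its median was 0.86 (adjusted p = 5.08e-06) without the 50% of genes with the lowest signals. Cytokines and receptors of the IL-17 and IL-22 axis differed by a median of 0.61 over 21 genes (camera, adjusted p = 3.84e-05; adjusted p = 0.39 with an estimated correlation), with 1 called higher over the list alone (0 without either vehicle array, 5 and 9 without MC903 replicate 1 and 2) and 0 over all genes. The neutrophil chemokine Cxcl5 stood at 29.4 and 41.9 in vehicle and at 1703 and 234 in MC903, and Il6 at 37.3 and 15.4 in vehicle, the second within the range of the TrpnX controls, and at 818 and 128 in MC903. That call ended when the 50% of genes with the lowest signals was left out (median 0.33, camera, adjusted p = 0.0941).

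With camera's preset correlation, though not with an estimated one, interferon response genes had the smallest p of the 40 lists. They were shifted upward by a median of 1.02 over 34 genes (camera, adjusted p = 1.34e-19, or adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone limma called 26 higher and 0 lower, against 0 over all genes and 4 higher with the intensity trend. The 26 came to 11 without vehicle replicate 1. The medians of the MC903 arrays were 1.04 and 1.13, and 31 members were higher in both MC903 arrays than in both vehicle arrays. Of the chemokines induced by interferon gamma, Cxcl11 differed by 2.30 ± 0.55 (1.56 without MC903 replicate 2). Cxcl9 stood at 7.72, within the range of the TrpnX controls, and 86.3 in vehicle and at 584 and 772 in MC903. Chemokines as a list differed by 1.17 over 35 genes (camera, adjusted p = 3.21e-09; adjusted p = 0.39 with an estimated correlation), 13 of them called higher over the list alone and 0 over all genes. The 13 came to 0 without vehicle replicate 1, 2 without vehicle replicate 2 and 5 without MC903 replicate 1. Acute phase and complement genes differed by 0.88 over 22 genes (camera, adjusted p = 8.11e-07; adjusted p = 0.39 with an estimated correlation), with 0 called over the list alone (13 higher and 1 lower without MC903 replicate 2) and 0 over all genes, and MC903 medians of 1.17 and 0.51. Among them the serum amyloid gene Saa1 stood at 32.7 and 47.1 in vehicle and at 2679 and 168 in MC903, and Saa3 differed by 3.15 ± 1.28 (1.37 without MC903 replicate 1, 4.93 without MC903 replicate 2).

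Leukocyte marker lists mostly had medians above 0 in both MC903 arrays, and for neutrophils and macrophages, unlike T cells, the 2 arrays differed widely. The neutrophil list shares S100a8 and S100a9 with the antimicrobial list and Hdc with the mast cell list. Neutrophil markers had a median of 1.11 over 21 genes (camera, adjusted p = 1.37e-06; adjusted p = 0.41 with an estimated correlation) and of 1.86 and 0.75 in the MC903 arrays. Limma called 3 of them higher over the list alone (0 without either vehicle array, 13 without MC903 replicate 2) and 0 over all genes, and S100a8 and S100a9 had the list's largest differences. Monocyte and macrophage markers differed by 1.06 over 29 genes (camera, adjusted p = 1.47e-07; adjusted p = 0.40 with an estimated correlation), 1.48 and 0.64 by array, with 0 called over the list alone (19 higher and 1 lower without MC903 replicate 2) and 0 over all genes. Cd163, a macrophage scavenger receptor, differed by 1.66 ± 0.67 and Fcer1g, a shared Fc receptor chain, by 1.44 ± 0.57 (0.71 and 0.64 without MC903 replicate 1). Dendritic cell and antigen presentation genes differed by 0.66 over 29 genes (camera, adjusted p = 6.6e-11; adjusted p = 0.39 with an estimated correlation), 0.78 and 0.59 by array, 2 being called higher over the list alone (0 without vehicle replicate 2 or MC903 replicate 1, 1 without vehicle replicate 1 and 4 without MC903 replicate 2) and 0 over all genes. Pdcd1lg2, the ligand PD-L2, differed by 2.07 ± 0.41 and the migration receptor Ccr7 stood at 38.5 and 7.77 in vehicle, the second within the range of the TrpnX controls, and at 157 and 72.4 in MC903. T cell markers differed by 0.72 over 24 genes (camera, adjusted p = 4.58e-07; adjusted p = 0.39 with an estimated correlation), 0.76 and 0.72 by array, with 7 called higher over the list alone and 0 over all genes. The 7 came to 3 without vehicle replicate 1 and without either MC903 array. Cd6 stood at 7.32 and 9.29 in vehicle and at 96.7 and 85.1 in MC903. Trat1 stood at 3.10 and 27.9 in vehicle and at 119 and 112 in MC903. Both vehicle signals of Cd6 and the first of Trat1 lay within the range of the TrpnX controls. The T cell call ended when the 50% of genes with the lowest signals was left out (median 0.18, camera, adjusted p = 0.0636). In the array with the higher neutrophil and macrophage medians the muscle markers lay lowest, at -1.68 against -0.13 in the other MC903 array.

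Innate lymphoid and natural killer cell markers differed by a median of 0.33 over 15 genes (camera, adjusted p = 0.00263; adjusted p = 0.39 with an estimated correlation), 0.55 and 0.43 by array, with Gzma, a granzyme, at 2.08 ± 0.79 (1.06 without MC903 replicate 1). Arg1, arginase 1, stood at 366 and 489 in vehicle and at 5124 and 578 in MC903, so that its difference of 1.99 ± 1.08 became 0.43 without MC903 replicate 1. B and plasma cell markers differed by 0.37 over 16 genes (camera, adjusted p = 0.00548; adjusted p = 0.39 with an estimated correlation), 0.12 and 0.26 by array, with Mzb1 at 1.08 ± 0.36 (0.67 without vehicle replicate 2) and Cd22 at 0.77 ± 0.27 (0.48 without MC903 replicate 1). Basophil markers differed by 0.50 over 10 genes (camera, adjusted p = 0.0055; adjusted p = 0.42 with an estimated correlation), 0.85 and 0.19 by array. Mcpt8, a basophil protease, stood at 4.67 and 4.21 in vehicle, within the range of the TrpnX controls, and at 2972 and 257 in MC903. The basophil call ended without MC903 replicate 1 (camera, adjusted p = 0.0866) and when the 50% of genes with the lowest signals was left out (0.21, adjusted p = 0.117). Mast cell markers differed by 0.34 over 17 genes (camera, adjusted p = 0.0417; adjusted p = 0.52 with an estimated correlation). Hdc, the histamine-forming enzyme, is also in the neutrophil list and differed by 2.24 ± 0.82 (1.07 without MC903 replicate 1, 3.42 without MC903 replicate 2). The protease gene Mcpt2 stood at 10.5 and 5.45 in vehicle, within the range of the TrpnX controls, and at 106 and 73.0 in MC903. The mast cell call ended without vehicle replicate 2 (camera, adjusted p = 0.0945) and without MC903 replicate 1, where the median was 0.06 (camera, adjusted p = 0.339). It also ended over members unique to the list (0.43, adjusted p = 0.114), with probe sets averaged (0.22, adjusted p = 0.0655) and with 1 added to each signal (0.34, adjusted p = 0.0671). Over the list alone limma called 1 mast cell gene higher and 0 of the innate lymphoid, B cell and basophil lists, against 0 over all genes for each. Without MC903 replicate 2 these counts were 4, 3, 0 and 5, and without either vehicle array they were 0. None of the T cell receptor genes listed for gamma delta T cells, such as Trdc and Trgc1, had a probe set named for it alone. That list therefore cannot say whether those cells changed. Not called by camera were the markers of eosinophils (median 0.40 over 9 genes, adjusted p = 0.132), Langerhans cells (0.12 over 10, adjusted p = 0.654) and gamma delta T cells (-0.11 over 7, adjusted p = 0.79, with median and test of opposite sign). In these lists the largest differences were those of Alox15 (2.06 ± 0.59) and Rnase2a (1.81 ± 0.61; 1.40 and 0.98 without vehicle replicate 2), of Dpep3 (-1.15 ± 0.22, with 1 MC903 signal, 14.7, within the range of the TrpnX controls) and Csf1r (0.68 ± 0.28, 0.33 without MC903 replicate 1), and of the granzymes Gzmb (2.37 ± 0.58, 1.56 without MC903 replicate 1) and Gzmc (1.76 ± 0.53, 1.01 without MC903 replicate 2).

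Vitamin D receptor targets were not called as a list (median 0.31 over 17 genes, camera, adjusted p = 0.0819). Their median was 0.19 without MC903 replicate 2 and 0.06 without MC903 replicate 1. Over the list alone limma called 2 higher and 1 lower (1 and 0 without vehicle replicate 2, 5 and 1 without MC903 replicate 2), and over all genes 0. Beside Cyp24a1, the phosphate transporter Slc34a2 stood at 258 and 218 in vehicle and at 1546 and 974 in MC903 (2.30 ± 0.28). The receptor gene itself, Vdr, differed by -0.21 ± 0.18. Lipid mediator synthesis genes had a median of 0.15 over 24 genes (camera, adjusted p = 0.0352; adjusted p = 0.39 with an estimated correlation), with 6 called higher and 1 lower over the list alone and 0 over all genes. The list-alone calls came to 0 without either vehicle array and to 3 higher without MC903 replicate 1. The lipoxygenase Alox8 differed by 3.47 ± 0.48 and Ptgs2, the inducible cyclooxygenase, by 2.72 ± 0.30. That call ended without vehicle replicate 1 (median 0.07, camera, adjusted p = 0.0514), without MC903 replicate 1 (median -0.03, adjusted p = 0.0915), over members unique to the list (0.09, adjusted p = 0.205) and without the 50% of genes with the lowest signals (0.12, adjusted p = 0.117).

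Mitotic cell cycle genes differed by a median of 0.75 over 41 genes (camera, adjusted p = 3.32e-10; adjusted p = 0.49 with an estimated correlation), 1.12 and 0.31 by MC903 array. Limma called 0 of them over the list alone and over all genes, and 30 over the list alone without MC903 replicate 2. Hmmr, a spindle-associated protein, differed by 1.32 ± 0.28, with 1 of its 4 other probe sets going the other way. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, differed by 1.21 ± 0.39 (0.70 without MC903 replicate 1). Matrix remodelling genes differed by 0.25 over 28 genes (camera, adjusted p = 0.0417; adjusted p = 0.65 with an estimated correlation), with 0 called over the list alone (10 higher without MC903 replicate 2) and 0 over all genes. The collagenase Mmp13 differed by 3.40 ± 0.63, and Timp1, an inhibitor of such enzymes, stood at 556 and 503 in vehicle and at 14719 and 1356 in MC903. The matrix call ended without MC903 replicate 1 (median -0.10, camera, adjusted p = 0.672), without vehicle replicate 2 (0.32, adjusted p = 0.135), with quantile normalization (0.30, adjusted p = 0.122), over members unique to the list (0.05, adjusted p = 0.192), without the 50% of genes with the lowest signals (0.01, adjusted p = 0.109) and with 1 added to each signal (0.33, adjusted p = 0.0638). Immediate early genes differed by 0.12 over 25 genes (camera, adjusted p = 0.0115; adjusted p = 0.60 with an estimated correlation). Ptgs2 was the 1 member called over the list alone (0 without either vehicle array), with 0 over all genes, and Fosl1, a Fos family factor, differed by 1.63 ± 0.36. Their call ended without MC903 replicate 2 (median -0.14, camera, adjusted p = 0.955), without vehicle replicate 1 (0.10, adjusted p = 0.075) and without the 50% of genes with the lowest signals (0.11, adjusted p = 0.117). Circadian clock genes were shifted downward by -0.32 over 17 genes (camera, adjusted p = 0.0151; adjusted p = 0.49 with an estimated correlation), with 0 called over the list alone and 0 over all genes. The clock repressors Per3 and Nr1d1 differed by -1.11 ± 0.20 and -0.81 ± 0.20. This call ended without MC903 replicate 1 (median -0.17, camera, adjusted p = 0.14) and without vehicle replicate 2 (-0.37, adjusted p = 0.0887).

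Skin samples also hold other tissue of the body wall or ear, and its markers did not move alike. Skeletal muscle markers differed by a median of -0.90 over 43 genes (camera, adjusted p = 5.81e-05; adjusted p = 0.61 with an estimated correlation), with 0 called over the list alone and 0 over all genes, but 24 lower over the list alone without MC903 replicate 2. Without MC903 replicate 1 the muscle call ended, with a median of -0.13 (camera, adjusted p = 0.234), and without vehicle replicate 1 the median was -0.58. The slow-fibre troponins Tnni1 and Tnnt1 differed by -2.33 ± 0.41 and -1.83 ± 0.54 (Tnnt1 by -1.09 without MC903 replicate 1). Adipocyte markers differed by 0.24 over 25 genes (camera, adjusted p = 0.00992; adjusted p = 0.65 with an estimated correlation), with 1 called lower over the list alone (0 without either vehicle array or without MC903 replicate 2, and 3 higher and 1 lower without MC903 replicate 1) and 0 over all genes. That list's call ended without MC903 replicate 2, at a median of -0.10 (camera, adjusted p = 0.955), and the 2 members with the largest differences went opposite ways. Pck1 differed by 1.41 ± 0.58 (0.75 without MC903 replicate 2, 0.92 without vehicle replicate 2), with 1 of its 2 other probe sets going the other way. Ucp1 stood at 30.4 and 34.6 in vehicle and at 4.58 and 5.58, within the range of the TrpnX controls, in MC903. Endothelial and pericyte markers differed by 0.13 over 28 genes (camera, adjusted p = 0.031; adjusted p = 0.60 with an estimated correlation), with 1 called higher over the list alone (0 without either vehicle array) and 0 over all genes. Their largest differences belonged to Sele and Selp, the selectins that capture leukocytes on vessel walls, at 1.94 ± 0.21 and 0.98 ± 0.18. The endothelial call ended without MC903 replicate 1 (0.13, camera, adjusted p = 0.176), without vehicle replicate 2 (0.04, adjusted p = 0.408) and without the 50% of genes with the lowest signals (0.11, adjusted p = 0.14).

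Camera called none of the lists of fibroblast and dermal matrix (median -0.06 over 28 genes, adjusted p = 0.339), cartilage (-0.19 over 26, adjusted p = 0.459), Schwann cell and nerve (-0.32 over 14, adjusted p = 0.126) or erythrocyte and platelet genes (0.07 over 10, adjusted p = 0.45). Without vehicle replicate 2 the first 3 of these were called lower by camera, with adjusted p of 0.0297, 0.034 and 0.0198. Over the list alone limma called 1 fibroblast and 2 cartilage genes lower, and 0 genes of the nerve, platelet, basal keratinocyte, sebaceous, tight junction, eosinophil, Langerhans and gamma delta T cell lists, against 0 over all genes for each. With any 1 array left out each of these lists gave at most 2 calls, and the cartilage list 0. The secreted Wnt modulators Sfrp2 and Sfrp4 went opposite ways, by -2.30 ± 0.27 and 1.204 ± 0.30 (Sfrp4 by 0.83 without vehicle replicate 2). In cartilage Col10a1 differed by 1.54 ± 0.37 and Cilp by -1.43 ± 0.22. In nerve the myelin gene Mbp differed by -0.90 ± 0.35 (-0.46 without vehicle replicate 1, and 2 of its 7 other probe sets went the other way) and Gfra3 by -0.89 ± 0.33 (-0.45 without MC903 replicate 1). Among platelet genes the chemokine Ppbp stood at 24.6 and 3.44, the second within the range of the TrpnX controls, in vehicle and at 81.8 and 34.5 in MC903. The chemokine Pf4 overlapped between the groups, at 2552 and 2065 in vehicle and at 8329 and 2443 in MC903.

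Arrays of one group were closer to each other than to arrays of the other group. Pearson's r across genes, which are not independent replicates, was 0.985 between the vehicle arrays, 0.975 between the MC903 arrays and 0.957 to 0.967 between groups. The first principal component held 59.6% of the variance and separated the groups, and the second held 24.7% and set the 2 MC903 arrays apart, at -30.4 and 40.6. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 1.24 to 1.27 for Actb and 0.638 to 0.671 for Gapdh. In 9044 genes, 49.7% of those tested, both MC903 arrays lay on one side of both vehicle arrays, against 33.3% by chance. Because genes move together, how far this share can stray from 33.3% without any treatment is not known.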

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

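All tests in this part were chosen after the results were seen. Among 10092 probe sets without a single gene name, which entered only the setting that tested probe sets singly, 53 were at least 2-fold higher and 62 at least 2-fold lower in all 4 pairings of an MC903 with a vehicle array. The other 2 splits of the arrays gave 36 and 44 such probe sets in all, against 115, and 2 against 2 arrays make too few splits to say whether chance is excluded. Among the 92 of those 115 with no gene symbol at all, ranked on the scale of log2(signal + 16), the first 2 upward were 1420465_s_at (52.1 and 28.7 in vehicle, 694 and 3137 in MC903, 4.761) and 1426154_s_at (1.33 and 4.71 in vehicle, 98.8 and 369 in MC903, 3.472), and the first 2 downward 1442425_at (802 and 1121, 54.0 and 22.8, -4.209) and 1437440_at (245 and 541, 39.3 and 1.15, -3.63). Both vehicle signals of 1426154_s_at and 1 MC903 signal of each of the downward ones lay at or below the signals of the TrpnX controls, so these sizes and ranks depend on the added constant. No test for a single outlying array was possible in groups of 2.

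The lower hair follicle signal is the first pattern a biologist would follow up. Fewer whole hair and sebaceous units would lower both. However, 7 genes taken as sebaceous gland markers had a median difference of 0.01459 (quartiles -0.09 and 0.13) against -2.56 for the hair follicle list. How far these 7 are particular to the gland was not tested. Awat1, Awat2, Dgat2l6 and Aadacl3 of the sebaceous list had no probe set named for 1 of them alone. The 7 genes therefore cannot exclude this explanation. Less deep tissue in the sample, with muscle genes as its markers, would make the hair follicle and muscle lists move together. Between the MC903 arrays, however, the hair follicle median differed by 0.2656 (replicate 1 minus 2) while muscle differed by -1.589. Between the vehicle arrays the 2 lists went opposite ways, by -0.71 and 0.76. Fewer follicles in the growth phase remains open as a hypothesis: genes of the hair shaft and inner root sheath (26 genes, median -3.29) lay below follicle stem cell genes (9 genes, median -0.57), with a difference of medians of -2.722. The fixed lists already held 7 of the 7 sebaceous, 26 of the 26 shaft and 5 of the 9 stem cell genes. The 26 came from the hair follicle list itself, which had shown the pattern. Of the 9, Krt15 is also in the basal keratinocyte list and Cd34 in the fibroblast list, and 7 lay lower in both MC903 arrays. How far the 9 are particular to the follicle was not tested, so the contrast cannot decide for a change of growth phase. Growth phase can differ between mice and between patches of skin, and 2 arrays per group leave open whether it followed the treatment.

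The MC903 arrays differed from each other in neutrophil markers, with a median of 1.40 for replicate 1 minus replicate 2 (quartiles 0.10 and 1.89). Array scaling would let the difference shrink under quantile normalization, where it was 1.39. Unequal RNA integrity would separate the 3′ to 5′ ratios of Actb or Gapdh, which differed by at most 0.038 on the log2 scale. Less muscle in replicate 1 would lift other cell types alike, and monocyte and macrophage (0.78, quartiles 0.18 and 1.22), basophil (0.71) and mast cell markers (0.49) did stand higher there with neutrophils, yet T cell and dermal matrix markers differed by at most 0.177 and adipocyte markers by -0.74 (quartiles -0.96 and -0.44). No biological explanation was tested, since the labels give no difference between the 2 MC903 samples.

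The third pattern is the count of 0 genes called by limma with a constant prior (2767 at an unadjusted p below 0.05) against 168 with a prior that follows the signal. Spread that falls with signal would favour the second prior, and the median residual SD of the dimmest 25% of genes (0.379) was 3.07 times that of the brightest 25% (0.124). A further candidate explanation is that genes with large differences varied more, and genes at least 2-fold apart in all 4 pairings had a residual SD 1.61 times that of other genes of like signal. Both are properties of these 4 arrays, and neither says which calls are true.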

How the results depend on the processing

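The signal-dependent count under other settings, the pairwise counts under added constants, filter, quantile normalization and left-out arrays, and camera with other scalings or constants were chosen after the data were seen. Limma with a constant prior called 0 genes either way (2767 at an unadjusted p below 0.05), but 3 higher and 0 lower both with quantile normalization and with arrays centred on their medians, 41 and 29 with 64 added, 25 and 17 without the dimmest 25% of genes, 96 and 81 without the dimmest 50%, 9 and 3 with probe sets averaged, 98 and 70 with the signal-dependent prior, and 15 and 6 at an adjusted p below 0.1. With a 2-fold limit as well these were 3 and 0, 3 and 0, 41 and 29, 25 and 17, 87 and 69, 9 and 3, and 90 and 65. It called 0 with 1 added, all probe sets, a robust prior, each array left out or a replicate block, which is no pairing in the labels. Same-numbered arrays deviated with a correlation of -0.061 across genes. With the signal-dependent prior the block gave 138 higher and 90 lower, and 158 of the 168 genes stayed called. That prior's count of lower genes was 115 without the dimmest 25% and 44 with probe sets averaged, and its counts ranged from 5 to 546 higher and from 0 to 400 lower with 1 array left out. The pairwise count of 211 higher and 148 lower became 602 and 527 at 1.5-fold, 45 and 61 at 4-fold, 401 and 316 with 1 added, 125 and 90 with 64 added, and 96 and 78 without the dimmest 50%. With 1 array left out, when only 2 pairings remain, it ranged from 415 to 659 higher and from 279 to 557 lower. Centring on medians gave 257 and 123. Camera's 25 lists higher and 4 lower became 0 and 0 with an estimated correlation, which also leaves the test 2 degrees of freedom. They became 0 and 0 with fry, and 16 higher without the dimmest 50%, where fewer genes are tested. Lower lists ranged from 2 to 6 with 1 array left out. The other settings gave 21 to 25 higher lists and 4 lower. Of 29 called lists, 19 stayed called with each array left out, the exceptions being named with their values beside the lists. Directions of the tests reversed in uncalled lists. With fry these were tight junctions (median -0.0409) and Langerhans cells (0.116), and without members of several lists Langerhans cells (-0.0853). With quantile normalization they were the sebaceous list (-0.0327), tight junctions (-0.0920) and Langerhans cells (0.0330). Medians of some lists called higher also turned negative, that of the itch list without members of several lists. Without MC903 replicate 1 they were -0.10 for matrix remodelling and -0.03 for lipid mediators. Without MC903 replicate 2 they were -0.14 for immediate early genes and -0.10 for adipocyte markers. With 1 array left out medians ranged from -0.119 to 0.0554 for tight junctions, -0.21 to 0.11 for fibroblasts, -0.47 to 0.10 for cartilage, -0.25 to 0.30 for the sebaceous list and -0.0944 to 0.146 for Langerhans cells. Gene differences ranged from -0.0570 to 1.22 for Flg, -0.0122 to 0.35 for Lor, -0.36 to 0.18 for Il5 and -0.0851 to 0.42 for Il31. Apart from the constructions named, the cause was not tested. The median difference of all genes was -0.04, and moved to -0.01 with quantile normalization and 0.04 with centring. Genes with signals near 24 or below, such as Il25, Il31 and Il5, cannot be told from background.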

Other observations

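Tests in this part were chosen after the values were seen, and so were the gene names that no earlier part gives. Families of genes that share the letters of their symbols were compared with the genes at least 2-fold apart in all 4 pairings, over 319 families of at least 8 measured members in each direction (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted). Genes are not independent replicates, so these p-values describe the makeup of the gene sets. Of 38 keratin-associated protein genes, which build the matrix of the hair shaft, 35 were lower (adjusted p = 5.01e-69). The keratins split, with 18 of 48 lower (adjusted p = 1.59e-23), among them Krt25, Krt71 and Krt86 of hair and root sheath, and 5 of 48 higher (adjusted p = 0.0182), namely Krt1, Krt16, Krt6b, Krt77 and Krt84. Small proline-rich genes were higher in 7 of 9 (adjusted p = 1.92e-10).

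Secreted proteases and inflammatory ligands made up further families. Of 20 kallikrein genes, whose proteases shed corneocytes, 5 were higher (Klk6, Klk7, Klk8, Klk9 and Klk13, adjusted p = 0.000344). Late cornified envelope genes were higher in 4 of 15 (adjusted p = 0.00231), and these were Lce3a, Lce3b, Lce3c and Lce3f, of the group known from epidermal repair. Of 13 Cxcl chemokine genes 5 were higher (Cxcl1, Cxcl5, Cxcl9, Cxcl10 and Cxcl11, adjusted p = 3.81e-05). Among 73 interleukin and interleukin receptor genes 6 were higher (adjusted p = 0.0182), including Il1b, Il1f6 and the keratinocyte-acting cytokine Il24. Members of one family are neighbours in sequence, and how far cross-hybridisation adds to these counts was not tested.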
